A study of Mus musculus with 3 samples.

How the data were processed

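FOXF1, a forkhead transcription factor needed for the lung mesenchyme and its blood vessels, was mapped by chromatin immunoprecipitation and sequencing in whole lungs of wild-type C57BL/6 mouse embryos at embryonic day 18.5. Per the labels, each of 2 biological replicates was a pool of 3 lungs, fixed in 1% formaldehyde. Chromatin was digested with micrococcal nuclease and sonicated, and 10 µg was precipitated with 7 µg of antibody. A 2% input of the same stage served as the control. The input entered only through the authors' peak calls, since a separate list for it was not analysed here.

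The authors called peaks with MACS2 on the mouse build mm10, per the submitters' processing notes, with 1 list for each replicate called against the input, per the peak names. The aligner, the MACS2 version and options, the treatment of duplicate reads and the sequencing depth are not given in the sources used here. Each deposited entry is the summit of 1 peak, a single base, with a score that is the authors' −log10 significance at the summit. Whether it is −log10 of a p or of a q value is not stated; the lowest scores were 2.04 and 2.02. Such a score depends on depth, so it was used to rank, describe and filter summits within a replicate, and its size was not compared between replicates. Exceptions are the paired scores of shared sites, compared in the last part, and the highest site of each named gene. For that highest site, the mean of both scores was followed over 4 settings and the gap between the scores served as the spread. No peak had more than 1 summit. Positions are 1-based and on mm10.

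Summits on chromosomes 1 to 19, X and Y were used, and the mitochondrial ones were set aside. A summit counted as shared when a summit of the other replicate lay within 100 bp. A shared site was a pair of summits that were each other's nearest, placed midway between them. Chance was the mean of 100 circular shifts of the summits along each chromosome, by at least 100 kb, and the test was one-sided with a smallest possible p of 0.0099. Spearman's rho of the scores was taken across shared sites, which are not independent replicates, so no p is given for it.

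Genes came from a RefSeq table of 49943 genes on the assembly GRCm38, the same assembly as mm10, of which 21887 are protein-coding. The table gives each gene's chromosome, start and end but neither strand nor exons, and no genome sequence was used. The planned distances to transcription start sites were therefore replaced by distances to either annotated end of a gene, and random positions by circular shifts of the sites. Exons, introns and untranslated regions were not told apart. The planned tests of forkhead and other sequence motifs, the matching on GC content and the removal of repeats need the sequence and were not run.

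Before the data were examined, 18 gene lists were fixed: endothelial cells, fibroblasts and matrix, smooth muscle and pericytes, epithelium, mesothelium, blood and immune cells, hedgehog, VEGF and angiopoietin, Notch, WNT, BMP and TGF-beta, FGF and PDGF, integrins and focal adhesion, genes linked to FOXF1 by earlier work, cell cycle, ribosomal proteins, neurons, and a list of photoreceptor, pancreas and sperm genes. Every listed symbol was found in the table. A gene had a site when a shared site lay within 5 kb of either end, and each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 18 lists. Adjusted p values under 0.05 were called. Each share carries an exact (Clopper-Pearson) 95% interval, and all such intervals cover counting error only.

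Several steps were added after the data were seen. Each list was compared with 10000 random lists matched on gene length and on the number of genes within 100 kb. Each shared site was assigned to the protein-coding gene with the nearest end within 100 kb, and the mean number of sites per gene was compared with matched random lists, two-sided. For these means 100000 random lists were drawn, which give a smallest two-sided p of 2.00e-05 before adjustment. That number was chosen because with 10000 lists the number of lists called lay between 10 and 12 over 21 draws. The hedgehog list was called in 20 of these draws and the WNT list in 17. Comparisons with matched lists are called permutation tests below, although their p comes from resampling genes outside the list, not from permuting membership. Pooled lists were compared on presence by Fisher's exact test and on number by a permutation test with 100000 resamples, after subtracting the mean of genes of similar length and local density. Intervals of these differences are percentile bootstrap intervals over genes. Lists share genes, such as Kdr in 3 of them, and neighbouring genes can share a site, so genes are not fully independent and these p values are approximate.

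The genes named were set by a rule fixed before the data were examined: Foxf1 and its neighbour Fendrr; the 10 protein-coding genes with the highest shared site within 5 kb, by the mean of the ranks of the score in both replicates; the 3 such genes of each list; the 5 genes with the most shared sites within the gene or 5 kb around it; and the 2 highest summits of each replicate with no summit of the other within 1 kb. In the ranking of highest sites, within 5 kb means within 5 kb of either end, so sites deeper inside a gene were not ranked. The part of the gene rule on the most shared sites was planned from 5 kb upstream, which needs a strand. Other genes are named where a list had few members with or without a site, or as examples of site numbers, and were chosen after their values were seen.

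Alternatives were shared distances of 50 bp and of 2 wider settings, a score of at least 10, the 10000 highest summits of each replicate, each replicate's own list, other distances to genes, and the ends of all annotated genes. Keeping the highest summit per peak changes nothing, since 0 peaks had several. The steps were tested on simulated data. With 0, 50 and 90% of 61172 summits truly shared, 0.97, 50.4 and 90.1% were found shared. The shares found were close to those planted, so nearly all planted partners lay within the shared distance. The simulation therefore checks the counting, and cannot show whether that distance captures the true partners in the data. There, the share of replicate 2 summits with a partner was 83.4% at the main distance and 90.2% at a wider one. Of 200 simulated lists of 28 genes among 21887, with 75% of list genes and 40% of other genes holding a site, 96.5% had an unadjusted p under 0.05, against 1% of lists with no difference. In the data 54.4% of protein-coding genes had a site, so a list at 75% would be called less often than in this simulation. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.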

Results

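FOXF1 binding sites were recorded in whole lungs of mouse embryos at embryonic day 18.5, shortly before birth, in 2 biological replicates that were each a pool of 3 lungs. The authors' list of replicate 1 held 107388 summits and that of replicate 2 held 61178, each called against the input. Of these, 107378 and 61172 lay on the nuclear chromosomes used here. The median summit score, the authors' −log10 significance, was 19.9 in replicate 1 and 17.6 in replicate 2. The read depth behind either list is not given in the sources used here.

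The question of the series was where FOXF1 binds in the fetal lung, and the replicates were compared first. Most regions bound in replicate 2 were also bound in replicate 1. Of the 61172 replicate 2 summits, 83.4% had a replicate 1 summit within 100 bp, against 0.865% by chance. Of the 107378 replicate 1 summits, 47.5% had a replicate 2 summit within 100 bp, against 0.491% by chance. Both shares exceeded all 100 circular shifts (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). Pairing left 51013 shared sites, whose paired summits lay a median of 13 bp apart. Both lists were called against the same input, and shifted summits do not keep to open chromatin. The shift test therefore cannot separate shared FOXF1 binding from shared background.

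Sharing followed the rank of the summit within its list. In replicate 1, 94.2% of summits in the highest score quintile were shared (95% exact interval 93.8 to 94.5%), against 2.25% in the lowest quintile (2.06 to 2.46%). In replicate 2, the share went from 68.4% in the lowest quintile (67.5 to 69.2%) to 91.7% in the highest (91.2 to 92.2%). The order of scores across shared sites was similar in both replicates, with Spearman's rho of 0.883 across sites, which are not independent replicates. The list lengths differed 1.76-fold, so a summit listed in replicate 1 alone cannot be read as a difference between the lungs.

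**Figure D1:**
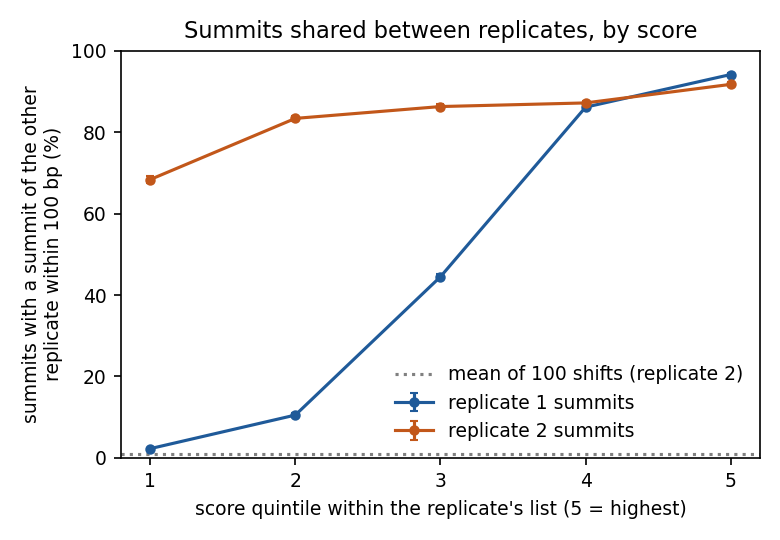
Percentage of each replicate's summits with a summit of the other replicate within 100 bp (vertical axis), by score quintile within its own list (horizontal axis, 5 is the highest), with exact 95% intervals and the mean of 100 circular shifts as a dotted line. Replicate 1 goes from 2.25% to 94.2% and replicate 2 from 68.4% to 91.7%.

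The highest summits without a partner had Txnip, Gna12 and Nr5a2 as their nearest genes. In replicate 1 these were at chromosome 3 position 96555266, 2691 bp outside Txnip, a regulator of glucose uptake and redox state, with a score of 203.3, and at chromosome 5 position 140791127, inside the G protein subunit gene Gna12, with a score of 184.6. In replicate 2 they were at chromosome 1 position 136784383, 58179 bp from the nuclear receptor gene Nr5a2, with a score of 149.5, and at chromosome 3 position 96557965, inside Txnip, with a score of 124.8. In these 4 cases the nearest summit of the other replicate lay 1247 to 2699 bp away, and Txnip had a summit of each replicate. Farther than 1 kb from any summit of the other replicate lay 44924 summits of replicate 1 (41.8%) and 1517 of replicate 2 (2.48%).

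Shared FOXF1 sites lay near the ends of protein-coding genes more often than shifted sites did, although most were distal. Of the 51013 shared sites, 17.2% lay within 1 kb of either end of a protein-coding gene, against a mean of 3.09% for shifted sites, a 5.58-fold difference (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). A further 44.7% lay inside a protein-coding gene beyond 1 kb from its ends, and 38.1% lay between genes. Sites over 100 kb from any gene end made up 17.9%, against 36.3% after shifting. The share near gene ends was 12.7% in the replicate 1 list and 18.98% in the replicate 2 list, and it fell to 9.16% among sites from the 10000 highest summits of each replicate. Gene ends here include both the start and the end of transcription, which were not told apart.

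The region within 100 kb of Foxf1 was among the more densely bound ones. On chromosome 8, Foxf1 spans positions 121084386 to 121088154 and its neighbour Fendrr, a long noncoding RNA gene, spans 121054882 to 121083110. Within 100 kb of Foxf1 there were 19 shared sites, of which 1 lay inside Foxf1 and 4 inside Fendrr. This amounted to 9.32 shared sites per 100 kb, against a median of 2.47 over protein-coding genes with windows drawn the same way, and was higher than in 98.5% of them. The density counts every site of the window. Foxf1 was the protein-coding gene with the nearest end for 12 of the sites, and 5 lay within Foxf1 or 5 kb around it.

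The highest site of the region lay at position 121127560, 39406 bp beyond the right end of Foxf1, with scores of 215.2 in replicate 1 and 106.0 in replicate 2. The next, at 121083244, lay 1142 bp to the left of Foxf1, between it and Fendrr, with scores of 168.1 and 90.9. Another at 121035732, to the left of Fendrr, had scores of 166.8 and 76.7. The site inside Foxf1, at 121086255, was far lower in both replicates, with scores of 15.0 and 9.39.

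**Figure D2:**
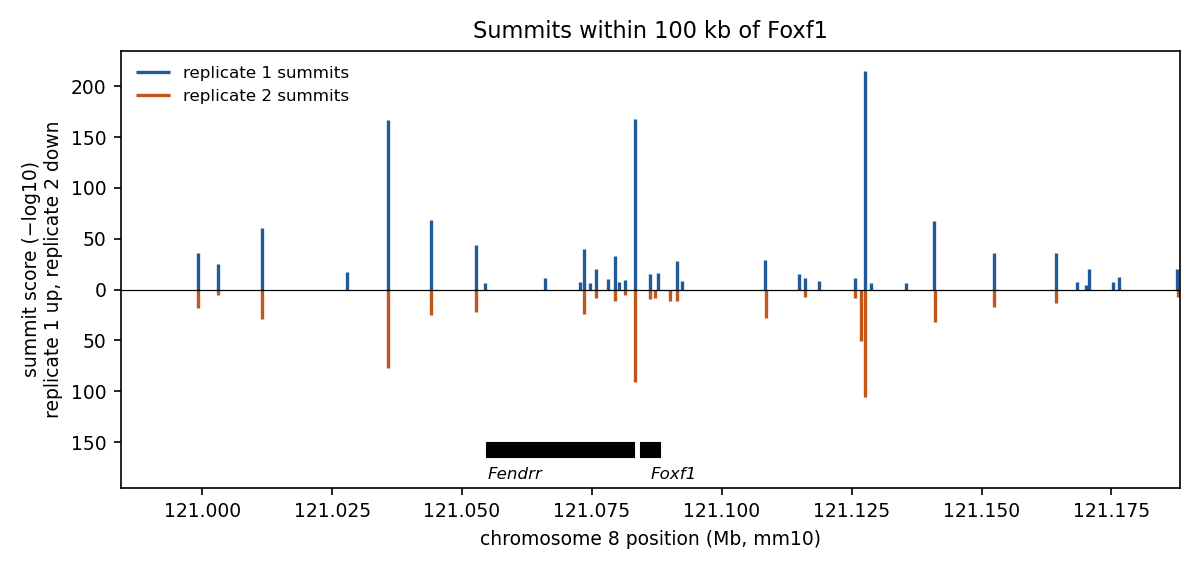
Summits of both replicates within 100 kb of Foxf1 on chromosome 8 (horizontal axis in Mb, mm10), with the summit score (−log10) drawn upward for replicate 1 and downward for replicate 2, and the spans of Fendrr and Foxf1 as black bars. The highest site, 39406 bp beyond the right end of Foxf1, has scores of 215.2 and 106.0.

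Markers of the endothelium carried FOXF1 sites almost throughout, and on average they carried several sites. Of 34 endothelial genes, 32 (94.1%, exact interval 80.3 to 99.3%) had a shared site within 5 kb of an end, against 54.3% of other protein-coding genes (Fisher's exact test, adjusted p = 6.16e-06). The exceptions were Eng and Mmrn2. The list averaged 9.35 sites per gene, against 2.34 in random lists matched on gene length and local gene density (permutation test, adjusted p = 9.00e-05). Kdr, the main VEGF receptor of endothelium, had 23 sites assigned to it, and S1pr1, a sphingosine phosphate receptor of endothelial barriers, had 25. Within 5 kb of an end of the list's genes, the highest site lay 3043 bp outside Car4, a carbonic anhydrase of lung capillaries, with scores of 235.3 and 110.1. Next came a site 1501 bp outside the endothelial lectin gene Clec14a, with 212.9 and 93.9. A site inside Kdr at chromosome 5 position 75974638 followed, with 189.7 and 104.2.

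Genes of fibroblasts and of smooth muscle and pericytes also carried sites more often than other genes. A site was present at 25 of 30 fibroblast and matrix genes (83.3%, Fisher's exact test, adjusted p = 0.0026) and at 20 of 24 smooth muscle and pericyte genes (83.3%, adjusted p = 0.0057). On average, sites were also more numerous than in matched lists. The means were 6.50 per fibroblast gene against 3.47 (permutation test, adjusted p = 0.0034) and 5.58 per smooth muscle gene against 2.73 (adjusted p = 0.0038). The medians were lower, at 4.5 and 3, and single genes held many sites, such as Foxp1 with 31 assigned to it and Mylk with 24. The highest fibroblast site lay 772 bp outside Tcf21, a transcription factor of lung mesenchyme, with scores of 143.7 and 67.8, followed by those of the intermediate filament gene Vim and the collagen gene Col6a3. Among smooth muscle and pericyte genes, Mcam, Cald1, which encodes the actin-binding protein caldesmon, and Srf, a transcription factor of contractile genes, had the highest sites. Fgf10, Dcn, Lum, Prrx1 and Col6a1 had no site within 5 kb of an end, nor had Cnn1, Actg2, Des and Myocd. Both lists lost their call when only the 10000 highest summits of each replicate were used. There 1 of 30 fibroblast genes and 2 of 24 smooth muscle genes had a site within 5 kb of an end (Fisher's exact test, adjusted p = 0.81 for each), and the endothelial list kept 19 of 34 (adjusted p = 1.31e-12). Strong sites farther away were not absent. By nearest gene end within 100 kb, these sites averaged 0.833 per fibroblast and smooth muscle gene, with 9 at Foxp1 and 5 at Cald1, and 2.88 per endothelial gene.

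Epithelial genes had sites about as often as fibroblast and smooth muscle genes, but fewer sites per gene than those lists. Of 28 epithelial genes, 24 had a site (85.7%, Fisher's exact test, adjusted p = 0.0020), led by Hopx, a marker of alveolar type 1 cells, whose site 977 bp outside the gene had scores of 207.4 and 93.1, by Etv5, a transcription factor of alveolar type 2 cells, with 160.4 and 81.6, and by Napsa, a protease of surfactant processing, with 118.8 and 49.4. The list averaged 2.07 sites per gene against 1.70 in matched lists, which was not a called difference (permutation test, adjusted p = 0.48). Lamp3, Cldn18, Foxa2 and Scgb3a2 had no site within 5 kb of an end. With only the 10000 highest summits of each replicate, 3 of 28 epithelial genes had a site and the call was lost (Fisher's exact test, adjusted p = 0.68).

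The pooled endothelial, fibroblast and smooth muscle genes were set against the epithelial genes directly. The share with a site was 87.5% of 88 genes against 85.7% of 28 (odds ratio 1.17, 95% interval 0.248 to 4.41; Fisher's exact test, adjusted p = 0.76). The number of sites per gene was 7.35 ± 6.97 (SD, 88 genes) against 2.07 ± 1.70 (SD, 28 genes). After subtracting the mean of genes of similar length and local density, the difference was 4.13 sites per gene (95% bootstrap interval 2.74 to 5.47; two-sided permutation test, adjusted p = 0.0013), and it was 1.08 with the 10000 highest summits of each replicate (permutation p = 0.0128). Endothelial genes exceeded fibroblast and smooth muscle genes by 4.04 sites per gene (1.52 to 6.50, permutation test, adjusted p = 0.0020). The pooled genes exceeded ribosomal and cell cycle genes by 3.83 (2.49 to 5.26, permutation test, adjusted p = 6.00e-05).

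Markers of other cell types gave lower shares. Of 25 blood and immune genes, 5 had a site (20.0%, Fisher's exact test, adjusted p = 0.0020), namely Coro1a, Mrc1, Cx3cr1, Spi1 and Cd8a. Of 28 neuronal genes 6 had a site (21.4%, Fisher's exact test, adjusted p = 0.0015), with the highest inside the splicing factor gene Rbfox3 at scores of 143.7 and 86.0, and then at Gap43 and Eomes. Of 26 genes of photoreceptors, pancreas and sperm 5 had a site (19.2%, Fisher's exact test, adjusted p = 0.0015), with the highest near the retinal gene Sag, the pancreatic gene Cpa1 and the photoreceptor gene Pde6a. Of 11 mesothelial genes 6 had a site (54.5%, Fisher's exact test, adjusted p = 1), led by Wt1, a transcription factor of mesothelium, by Upk1b and by Podxl. Neuronal genes averaged 1.43 sites against 3.13 in matched lists (permutation test, adjusted p = 0.0179), while the means of blood (0.84 against 1.57), mesothelial (3.18 against 2.72) and photoreceptor list genes (0.731 against 1.11) were not called. All 3 lower calls were lost within 20 kb (Fisher's exact test, adjusted p = 1 for blood and immune, 0.0541 for neurons and 0.173 for the photoreceptor list). The blood and neuronal calls were also lost with the list of replicate 1 alone (Fisher's exact test, adjusted p = 0.141 and 0.0757) and by nearest gene end (0.0759 and 0.263).

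Genes of growth, used in every tissue, also had sites. All 28 ribosomal protein genes had a site (100%, exact interval 87.7 to 100%, adjusted p = 8.61e-07), with the highest at Rplp0, Rpl3 and Rps9, and the list averaged 1.18 sites per gene against 0.759 in matched lists (adjusted p = 0.20). Of 29 cell cycle genes 24 had a site (82.8%, Fisher's exact test, adjusted p = 0.0037), led by the cyclin-dependent kinase inhibitor gene Cdkn1b, the replication helicase gene Mcm7 and the cyclin gene Ccne2, at 2.28 sites per gene against 1.36 (adjusted p = 0.0469). With the 10000 highest summits of each replicate, 2 of 28 ribosomal and 3 of 29 cell cycle genes had a site, and both calls were lost (Fisher's exact test, adjusted p = 1 and 0.68). The cell cycle call was also lost at a score of at least 10 (Fisher's exact test, adjusted p = 0.11).

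**Figure D3:**
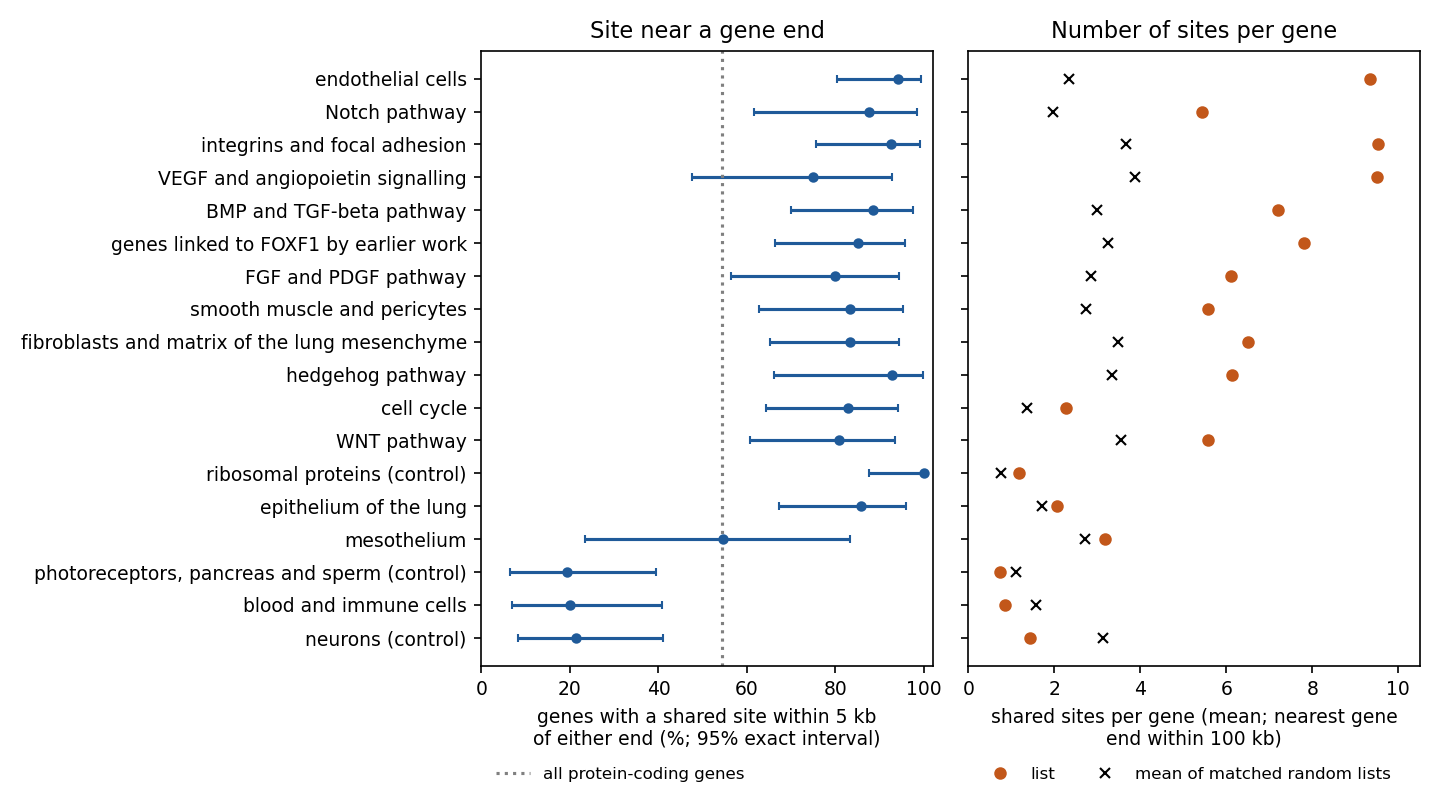
Left, percentage of the genes of each of 18 lists with a shared site within 5 kb of either gene end, with exact 95% intervals and all protein-coding genes (54.4%) as a dotted line; right, mean shared sites per gene in each list (circles) and in matched random lists (crosses). Endothelial genes stand at 94.1% and 9.35 sites per gene, and ribosomal protein genes at 100% and 1.18.

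Among the signalling pathways, sites were frequent at genes of adhesion, BMP and TGF-beta, hedgehog, Notch and WNT signalling. By Fisher's exact test, a site was present more often than at other genes at 25 of 27 integrin and focal adhesion genes (92.6%, adjusted p = 1.35e-04), 23 of 26 BMP and TGF-beta genes (88.5%, adjusted p = 0.0013), 13 of 14 hedgehog genes (92.9%, adjusted p = 0.0069), 14 of 16 Notch genes (87.5%, adjusted p = 0.0117), 21 of 26 WNT genes (80.8%, adjusted p = 0.0116) and 16 of 20 FGF and PDGF genes (80.0%, adjusted p = 0.0269). The VEGF and angiopoietin list had a site at 12 of 16 genes, which was not called (75%, Fisher's exact test, adjusted p = 0.14), although its mean of 9.50 sites per gene exceeded the 3.88 of matched lists (permutation test, adjusted p = 8.64e-04). Its presence was called by Fisher's exact test with the 10000 highest summits (adjusted p = 2.15e-04), with either replicate alone (0.0422 and 0.0377), by nearest gene end (0.0269), for sites anywhere in the gene or 5 kb around it (0.0082) and at a wider shared distance (0.0258). By Fisher's exact test it stayed uncalled at 50 bp (adjusted p = 0.0812), at a score of at least 10 (0.0577), within 1 kb (0.329) and within 20 kb (0.195), and also against matched lists (0.324).

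In the adhesion list, Itga2, which encodes a collagen-binding integrin subunit, had a site 439 bp inside its end with scores of 259.5 and 135.4, followed by a site at Itgb1 and by a site 3404 bp outside the focal adhesion gene Pxn. The Pxn site is the one named above for the ribosomal gene Rplp0, which it lies 76 bp from, and within 1 kb of Pxn the highest site had a mean score of 12.8 instead of 106.9. In the BMP and TGF-beta list, the signal transducer gene Smad5 led with 218.5 and 104.2, followed by Acvrl1, an endothelial receptor of the pathway, with 163.1 and 85.3, and by the inhibitor gene Smad7. The FGF and PDGF list was led by Dusp6, a phosphatase that limits ERK signalling, whose site 169 bp outside the gene had 218.0 and 125.7, then by Etv5 and the growth factor gene Pdgfb. The VEGF and angiopoietin list was led by Kdr, by Tek, the angiopoietin receptor, at 171.9 and 103.3, and by its ligand gene Angpt2. Notch sites were highest at Mfng, Notch4 and Hes1 (whose mean score was 19.9 instead of 104.3 at a shared distance of 50 bp), WNT sites at Wif1, Lrp6 and Fzd4, and hedgehog sites at Gas1, Smo and Ptch1.

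By permutation, the number of sites per gene exceeded that of matched lists for integrins and focal adhesion (9.52 against 3.66, adjusted p = 9.00e-05), BMP and TGF-beta (7.19 against 2.98, adjusted p = 9.00e-05), Notch (5.44 against 1.98, adjusted p = 0.0022) and FGF and PDGF (6.10 against 2.85, adjusted p = 0.0034). Hedgehog (6.14 against 3.35) and WNT (5.58 against 3.55) lay at the threshold, each with an adjusted p of 0.0469. With the 10000 highest summits of each replicate, integrin, BMP and TGF-beta, WNT and VEGF genes had sites more often than other genes, while the hedgehog, Notch and FGF and PDGF calls were lost (Fisher's exact test, adjusted p = 1, 0.0573 and 0.107). Other settings ended the hedgehog call at a score of at least 10 (Fisher's exact test, adjusted p = 0.12), the WNT call within 1 kb (0.263) and with replicate 1 alone (0.0748), and the FGF and PDGF call within 20 kb (0.18) and against matched lists (0.056).

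Of 27 genes linked to FOXF1 by earlier work, 23 had a site (85.2%, exact interval 66.3 to 95.8%, adjusted p = 0.0026), at 7.81 sites per gene against 3.25 in matched lists (adjusted p = 9.00e-05). Besides Kdr and Tek, the paralogue Foxf2 had a high site, 1167 bp outside the gene, with scores of 201.9 and 87.1. Cxcl1, Nfia, Myocd and Gli1 had none within 5 kb of an end, although Nfia had 34 sites and Myocd 4 farther inside the gene. Several genes of this list are also in the endothelial list, so the lists are not independent.

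Over all protein-coding genes, the highest site within 5 kb of a gene end lay 808 bp inside Ackr4, an atypical chemokine receptor gene. It lay at chromosome 9 position 104098490, with scores of 289.9 and 178.3. Alkbh3, a nucleic acid demethylase gene, followed with 282.6 and 151.6, and Calr4 with 271.1 and 156.6. The summits of the Calr4 site lay 90 bp apart, and at a shared distance of 50 bp the mean score of the highest Calr4 site was 45.3 instead of 213.8. A single site on chromosome 6 at position 129425352 lay within 5 kb of the C-type lectin genes Clec12b, Clec1a and Clec9a, with scores of 271.1 and 146.5. Sites of the growth hormone receptor gene Ghr (291.3 and 136.6), of Arap2 (263.8 and 146.5) and of the neighbours Prpf4 and Rnf183, which share a site (265.3 and 141.8), completed the first 10. The genes with the most shared sites within the gene or 5 kb around it were Arhgap26 with 78, Lrmda with 55, Wwox with 53, the forkhead gene Foxp1 with 52 and Frmd4a with 51, counts not corrected for gene length. The highest site of a gene depends on the 5 kb window. Within 1 kb of an end 23 of the 66 named genes had no site, and in 16 the mean score of the highest site was lower by over 1.5 times. It was 9.79 instead of 153.4 for Clec14a, 69.9 instead of 146.9 for Kdr, 27.997 instead of 217.1 for Alkbh3, 31.9 instead of 203.5 for Prpf4, 42.5 instead of 144.5 for Foxf2, 49.8 instead of 124.2 for Acvrl1 and 22.7 instead of 84.1 for Napsa. The others were Angpt2, Col6a3, Lrp6, Mcam, Mcm7, Mfng, Pdgfb, Ptch1 and Pxn. Within 20 kb it was higher by as much for Mrc1 (156.4 instead of 32.3), Foxp1, Frmd4a and Ptch1.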

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

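Every test in this part was chosen after the summits were seen. Mitochondrial summits, which no comparison above used, were present in both lists, 10 in replicate 1 and 6 in replicate 2. Of the replicate 1 summits, 4 lay within 100 bp of a replicate 2 summit, against a mean of 0.718 over 1000 circular shifts (one-sided permutation p = 9.99e-04, the smallest that 1000 shifts can give). The highest scores there were 43.4 and 13.97. The counts are small, and both lists were called against the same input. Whether these summits are FOXF1 binding was not tested, and agreement between the lists does not show it.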

How the results depend on the processing

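The matched lists, the sites per gene, the cell type comparison and the presence of a site anywhere in a gene were chosen after seeing the data; the other tests here were planned. The shares of shared summits, the share of sites near gene ends and the cell type comparison kept their direction and side of the threshold in all settings run. Without replicate 1 or replicate 2, the share near gene ends ranged from 12.7 to 18.98%, the enriched lists from 13 to 14, the lists with more sites per gene stood at 11 and the cell type difference ranged from 5.06 to 7.12 sites per gene. The correlation of scores between replicates across shared sites was 0.880 at a wider shared distance, 0.851 at a score of at least 10 and 0.822 with the 10000 highest summits. The score cut and the choice of the highest summits both narrow the range of scores. For the wider distance the cause was not tested. With the 10000 highest summits 6 lists were enriched rather than 13, and 7 rather than 12 had more sites per gene; fewer sites were tested there. The same setting turned the difference from other genes to -3.69 percentage points for fibroblasts and to 0.67 for the photoreceptor list, neither called. The uncalled mesothelial difference, near 0 in 11 genes, turned to -4.63 (50 bp), -4.58 (wider distance), -4.35 (score of at least 10), -6.28 (without replicate 1, against 5.33 without replicate 2), -5.43 (20 kb), -4.19 (nearest gene end), -6.05 (site in or around the gene) and -5.87 points (matched lists); the cause was not tested. Over the lists and settings, 160 results kept their direction and side of the threshold, 24 lost (3 of them lower calls that the 10000 highest summits are too few to give) and 6 gained a call, and 8 uncalled ones turned. For the highest sites of 66 named genes over 4 settings, the mean score stayed between the scores of both replicates in 214 results and did not in 26. The mean of an unchanged site always lies between its own scores, and scores differ between the lists, so this count is a loose measure. Within 1 kb 23 of these genes had no site, Foxf1, Car4, Smad5 and Wif1 among them, and at 50 bp Itgb1 had none. The motif, repeat and GC alternatives were not run, for lack of a sequence. The overlap and rho have no value without a replicate. No paired analysis was possible because the input has no list of its own to pair with a replicate. Unknown depth limits how far summits in 1 replicate alone can be read.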

Other observations

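The comparisons among the strongest sites, the gene families, the replicate-only sites, the X chromosome, the blood and mesothelial genes, the quintiles of replicate 2 and the numbers of sites per gene in this part were chosen after the data were seen; the other tests on list length and on presence of a site were written before their values were seen.

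Among the strongest sites, endothelial genes had a site within 5 kb of an end more often than fibroblast and smooth muscle, epithelial, or ribosomal and cell cycle genes. The signalling lists and the mesothelium were not compared with them. Taking the 10000 highest summits of each replicate gave 7513 shared sites, and 7.02% of protein-coding genes had such a site within 5 kb of an end. Of 34 endothelial genes 19 did (55.9%), against 3 of 54 fibroblast and smooth muscle genes (odds ratio 20.6, 95% interval 5.11 to 123.3; Fisher's exact test, adjusted p = 4.76e-07), 3 of 28 epithelial genes (odds ratio 10.1, adjusted p = 3.86e-04) and 5 of 57 ribosomal and cell cycle genes (odds ratio 12.7, adjusted p = 3.98e-06). Among the endothelial genes were Kdr with 11 of these sites assigned to it, the VEGF receptor gene Flt1 with 8, Tek and the endothelin receptor gene Ednrb with 7 each, and Fli1, an endothelial transcription factor gene, and Cldn5, a tight junction gene, with 6 each. Assigned by nearest gene end, these sites averaged 2.88 per endothelial gene, against 0.833 per fibroblast and smooth muscle gene, and the contrast by this count was smaller. Foxp1 of the fibroblast list had 9 and Cald1 of the smooth muscle list 5. The mean was 0.357 per epithelial gene and 0.228 per ribosomal and cell cycle gene. Over all 51013 sites, counting those over 5 kb from a gene end, endothelial genes averaged 6.82 per gene, against 1.63 in matched lists (permutation test, adjusted p = 1.80e-04), and epithelial genes 0.893, against 1.07 (adjusted p = 0.84). In all, 9 of the 18 lists had more such sites, among them fibroblasts (4.97 against 2.66, permutation test, adjusted p = 0.0136), smooth muscle (4.25 against 1.93, adjusted p = 0.0126), and integrins and focal adhesion (7.52 against 2.77, adjusted p = 1.80e-04). Sites within 1 kb of a gene end were most frequent in the quintile of shared sites next to the highest (23.6%) and less so in the highest (13.9%).

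Of the 10 highest shared sites of the genome, 5 lay inside protein-coding genes and 5 between them. The highest was inside Upf2, a gene of nonsense-mediated decay, at chromosome 2 position 6015217, with scores of 354.5 and 231.9, and others lay inside Kif13a, Raver2, Lrmda and Foxp1. Another lay 100205 bp from Tbx3, a T-box transcription factor gene, and another 16683 bp from Adamts9. Of the 1517 replicate 2 summits over 1 kb from any replicate 1 summit, 49.4% lay within 5 kb of a gene end, against 28.8% of shared sites. Within 1 kb of an end the shares were alike, at 17.3% and 17.2%. Of the 44924 replicate 1 summits over 1 kb from any replicate 2 summit, 16.98% lay within 5 kb, against 12.8% for shifted shared sites.

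Gene families, taken as symbols with the same stem and at least 10 members, differed widely. Of 281 stems, 57 had sites more often and 51 less often than other genes by Fisher's exact test with adjustment, and 35 and 46 did against lists matched on gene length and local density. Few olfactory receptor genes (Olfr, 23 of 1110) and vomeronasal receptor genes (Vmn, 3 of 355) had a site within 5 kb of an end, and few cytochrome P450 genes did (Cyp, 21 of 99). Sites were frequent at zinc finger genes (Zfp, 287 of 397) and at vacuolar protein sorting genes (Vps, 34 of 35). Of the clustered protocadherins, none of 22 Pcdhb genes had a site, while 12 of 12 Pcdha genes did, which overlap in the genome and share an end. All 12 Pcdhga genes had a site as well. In the permutation test against matched lists, the Pcdhb difference stayed called (adjusted p = 0.0018), but those of Pcdha (0.0731) and Pcdhga (0.13) did not.

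Replicate 1 had 1.76 times as many summits as replicate 2. Whether a lower depth or enrichment in replicate 2 accounts for this stays open. The share of replicate 1 summits found in replicate 2 was 91.9 percentage points higher in the highest score quintile than in the lowest, past the mark of 20 points set for it, but the share of replicate 2 summits found in the longer replicate 1 list passed the same mark, with 23.4 points. At the shared sites, replicate 1 had the higher score in 98.1% of pairs, with a median ratio of 2.29 to the replicate 2 score. A lower depth or enrichment in replicate 2 could give this gap, but its cause was not tested. The libraries' depths are not given in the sources used here, so depth and enrichment were not separated. A biological difference between the pools was not tested.

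Most lists had sites near gene ends more often than other genes. Gene length and local gene density are argued against as the whole cause, as 12 of the 13 enriched lists, ribosomal and cell cycle genes among them, kept an adjusted p under 0.05 against matched lists, and the difference in number of sites between mesenchymal or endothelial and epithelial genes remained 4.13 after the same correction. For open chromatin of all lung cells alike, blood and immune genes were compared. Of these, 20.0% had a site against 87.5% of mesenchymal and endothelial genes (Fisher's exact test, odds ratio 26.6, adjusted p = 7.70e-10). The 54.5% of 11 mesothelial genes was also lower (Fisher's exact test, odds ratio 5.68, adjusted p = 0.0252). This cannot decide the question, because markers of cells that are few in the pools could have few sites either way. The share of these cells in the pools was not measured. General occupancy of active genes could contribute, since 91.2% of ribosomal and cell cycle genes had a site (Fisher's exact test against the mesenchymal and endothelial genes, adjusted p = 0.74). Open chromatin of the epithelium cannot be told apart from it, because the 85.7% of 28 epithelial genes has a wide interval (67.3 to 96.0%).

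The X chromosome had 12.3 replicate 1 summits per Mb, against an autosomal median of 42.3 and a lowest autosome of 38.2, and in replicate 2 it had 7.31 against a median of 24.0. Fewer genes are not the whole cause, since the X had 1.10 shared sites per protein-coding gene (95% Poisson interval 1.04 to 1.17) against 1.32 on chromosome 7, the lowest autosome. The labels do not give the sexes of the pools. A lower X copy number would have to lower the count to 0.322 of the lowest autosome, below the ratio of 0.570 between the replicate lists. This argues against copy number as the whole cause only as far as copy number acts like the gap between the lists, which was not measured. Shared sites on the X had a median replicate 1 score of 35.7, against 42.2 on the lowest autosome, which a lower copy number could also give. Repeats and mappability of the X were not tested and may contribute beside the 0.322.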
